A study of Mus musculus with 4 samples.

How the data were processed

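RNA was measured in 4 libraries of freshly isolated mouse muscle stem cells (satellite cells), 2 from Control animals and 2 from animals with a conditional knockout (cKO) of Rbfox2. Per the labels' protocols, RNA was extracted with a low-input column kit, 10 ng of each sample went into the library, cDNA was made by the SMART-Seq protocol and libraries were built with an MGI kit. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.6 and the build GRCm38, with no role or order. The strand setting, the annotation release and any filters are not given in the sources used here. SMART-Seq cDNA does not mark strand unless a step is added for it, so reads of overlapping genes on opposite strands may not have been separated.

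The deposited count table holds estimated counts per gene, already whole numbers, so no further rounding was needed. Among genes with a single annotated transcript and over 200 counts, between 98.7% and 98.9% had a count within 1% of a constant times the TPM times the transcript length in each library. Counts derived from transcript coverage would give this, as would TPM computed from counted reads, so the match alone does not tell them apart. The deposited counts were treated as derived from transcript coverage. In that case a shift in coverage between transcripts or between copies of a sequence can move them. The second deposited table gives TPM, a transcript abundance per gene, corrected for transcript length and scaled to the same sum in each library, a unit that keeps no depth. Because the TPM are per gene, the planned comparison of transcript usage, for Rbfox2, Numb and Rbfox splicing targets, was not run.

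Both tables list 55487 genes by versioned Ensembl identifier. GENCODE M21 on GRCm38 supplied symbols, coordinates and biotypes, and 55394 identifiers matched it without the version. The total estimated count was 84869830 and 85499716 in Control 1 and 2, and 68884091 and 101997422 in cKO 1 and 2. At this depth the spread between libraries, not counting error, limits most comparisons: the common biological coefficient of variation was 0.373.

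The libraries of a group were first checked for being separate. A chi-square of their scaled counts over genes with a mean count of at least 20 gave a statistic over degrees of freedom of 49.6 for Control and 83.4 for cKO, rising with the count, so they were treated as separate libraries. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The library codes in the labels have a part, L01 or L02, that same-numbered Control and cKO libraries share, of the form used for a sequencing lane. The last part of the code is the same in both libraries of a group and differs between the groups. What it marks therefore cannot be told apart from genotype. The libraries of a group differ in their codes only in the L01 or L02 part. The labels do not say what either part or the replicate number marks, and none was a term in the model. A fit with the replicate number, and so the L01 or L02 part, as a block was an alternative.

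Counts were compared with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr and the robust quasi-likelihood test. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE of a log2 fold change is the size of the fold change divided by the square root of its F statistic. Normalised counts are CPM computed with the TMM-scaled library sizes. The TPM were compared with limma 3.58.1 (trend, robust) on log2(TPM + 1) for genes with a mean TPM of at least 1. Its fold changes are on that scale, which understates changes of low genes.

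Before the data were examined, 30 gene lists were fixed for Rbfox and Notch biology, myogenic state, signalling, metabolism and other cell types in muscle. The 29 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. The same test with an estimated correlation, and fry, were alternatives. A rule fixed at the same time chose the genes named. It takes 13 Rbfox, Notch and myogenic genes always. It takes the 12 higher and 12 lower genes with the largest fold change among called genes with a mean CPM of at least 4, no overlap between the groups and a symbol of a named gene. For each list it takes up to 4 called members with the smallest adjusted p, or up to 3 with the highest mean CPM if none was called. Other genes named were chosen after their values were seen. Values of some list members are not reported here.

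The alternatives were DESeq2 size factors or no factor beyond the library total in edgeR, no filter on low counts, a CPM of at least 5 in 2 libraries, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, other thresholds, and other pseudocounts and filters for the TPM. The scripts were tested on simulated data drawn from these libraries' means and spread, with 36116 genes tested. The edgeR step recovered 10% of 50 genes changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold and of 50 changed 16-fold, with 7 false calls. With no gene changed it made 0 calls. A camera list shifted on purpose was called and 0 of 19 unshifted lists were. The simulated genes varied independently of each other, and the changed genes were picked among those with a mean CPM of at least 4. Simulated libraries of a group differed only by size and independent spread, with no shift over many genes between them. The recovered shares and the number of false calls therefore need not hold for lower genes or for libraries with such a shift. In these libraries the estimated inter-gene correlation was 0.87 for nuclear oxidative phosphorylation genes and 0.99 for mitochondrially encoded genes. The simulation therefore did not check camera for lists whose genes move together.

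For genes that were called, and for the same number of genes not called with the same biotype and the nearest mean CPM, the share of 50-mers found in transcripts of other annotated genes was computed from the GENCODE M21 transcripts. A gene was counted as sharing sequence when another gene held at least 20% of its 50-mers. Exon overlap means at least 100 bases shared with another gene on either strand. Unannotated copies were not searched.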

Results

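Gene expression was measured by RNA-seq in satellite cells, the Pax7-expressing stem cells of skeletal muscle, taken directly after isolation from 2 Control and 2 Rbfox2 cKO samples. Rbfox2 is an RNA-binding protein that regulates alternative splicing, and the study addresses its part in the splicing of Numb and in Notch signalling. Each library held between 68884091 and 101997422 estimated counts. The cKO 1 library had the smallest total and a higher low-level background than the other 3. Its median TPM over all genes was 0.771, against 0.392 and 0.437 in Control and 0.312 in cKO 2. The median TPM of 1739 olfactory and vomeronasal receptor genes was 0.679 in cKO 1, against 0.340 and 0.407 in Control and 0.239 in cKO 2. The first principal component held 44.2% of the variance and separated cKO 1 from cKO 2, with both Control libraries between them. The second held 29.4% and separated the groups, at -62.3 and -51.6 in Control 1 and 2 and 65.5 and 48.4 in cKO 1 and 2.

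The targeted gene was lower in both cKO libraries. Rbfox2 (ENSMUSG00000033565.18; GRCm38 chromosome 15, 77078990 to 77307004, minus strand) stood at 131.3 and 55.98 CPM in Control 1 and 2 and at 40.04 and 15.17 CPM in cKO 1 and 2. It fell with a log2 fold change of -1.76 (SE 0.35), from 93.6 ± 53.3 to 27.6 ± 17.6 CPM (SD, n = 2 each), with an adjusted p = 0.000252 in edgeR's quasi-likelihood test. Reads outside the deleted exons may remain in a gene total, so the residual level does not measure intact transcript. The call was lost when any 1 library was left out, with log2 fold changes from -2.61 to -1.04, in limma on TPM (-1.16, adjusted p = 0.237), with library totals only (-1.47), with no filter on low counts (-1.81) and with a CPM of at least 5 in 2 libraries (-1.52). The paralog Rbfox1 stood at 1.45 ± 0.10 CPM in Control and 2.25 ± 0.29 CPM in cKO (SD, n = 2 each; adjusted p = 1.00).

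The question of the series title, whether Notch signalling differs without Rbfox2, was addressed at the level of gene totals. None of the Notch or myogenic genes fixed for this passed the threshold with all 4 libraries. Hes1, a direct Notch target, stood at 21.2 ± 11.1 CPM in Control and 40.5 ± 0.33 CPM in cKO, a log2 fold change of 0.94 (SE 0.33, adjusted p = 0.346). Pax7, the transcription factor that marks satellite cells, stood at 24.6 ± 2.70 and 44.1 ± 7.36 CPM (log2 fold change 0.84, SE 0.33, adjusted p = 0.556). Notch1 stood at 47.4 ± 2.67 and 76.4 ± 5.11 CPM (0.69, SE 0.34, adjusted p = 0.975). For Hes1, Pax7, Notch1, Notch3 and Heyl, both cKO libraries lay above both Control libraries, and for Hey1 and Myog both lay below, an arrangement that 2 against 2 samples give in one direction or the other by chance in 33.3% of cases. The log2 fold change was 0.58 for Heyl, 0.46 for Notch3, -0.40 for Hey1, -0.15 for Notch2 and -0.18 for Numb, the endocytic Notch inhibitor. The myogenic regulators Myod1 (0.02), Myf5 (-0.18) and Myog (-0.63) did not pass either. Hes1 depended on the Control libraries, at 0.47 without Control 1 and 1.58 without Control 2. With cKO 1 left out, the log2 fold change was 1.01 for Pax7, 0.75 for Heyl and 0.77 for Notch1. With cKO 2 left out, it was -0.81 for Hey1. Such fits leave 1 cKO library and do not measure the spread within cKO. Numb, Notch2 and Myf5 turned positive without cKO 1, at 0.10, 0.16 and 0.19. The simulated data showed that 2-fold changes were recovered in 10% of cases, so changes of this size were mostly not detectable with these libraries.

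**Figure D1:**
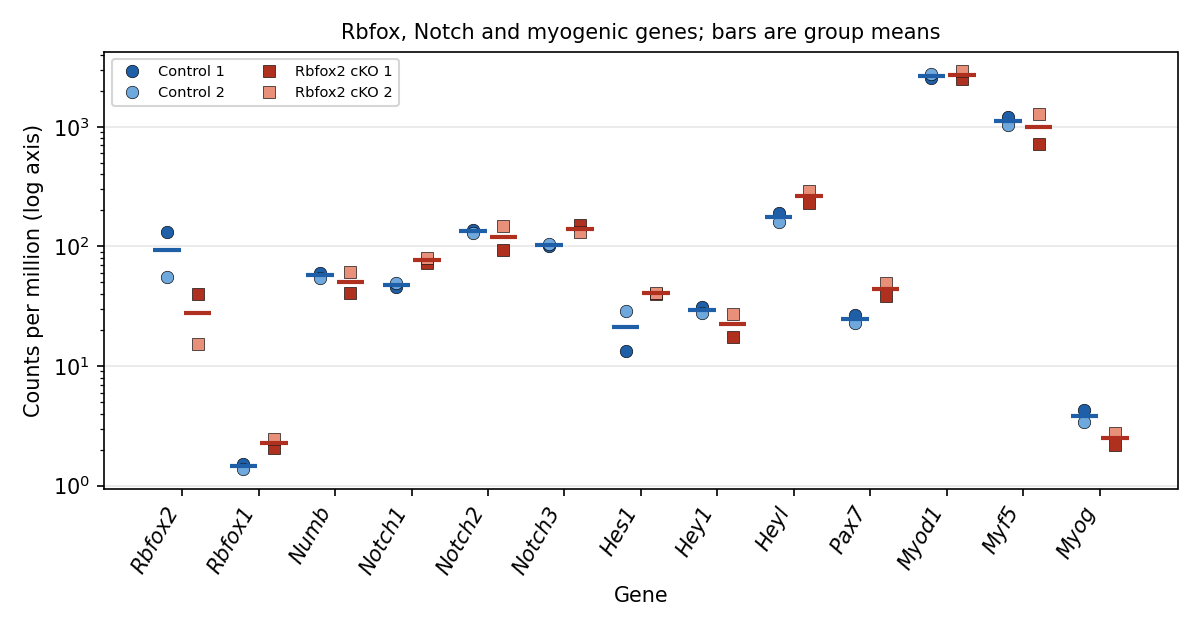
Normalised read counts (CPM) on a log axis for the 13 Rbfox, Notch and myogenic genes, with circles for the Control libraries, squares for the Rbfox2 cKO libraries and bars for group means. Rbfox2 has a lower cKO mean (27.6 against 93.6 CPM), and Myod1 has nearly the same mean in both groups (2662 and 2703 CPM).

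Of 38143 genes tested in edgeR, 139 rose and 71 fell in cKO. At an unadjusted p under 0.05 there were 1842, less than a share of 0.05 of the genes tested. Chance alone would give a share of 0.05, so this number shows no broad set of weaker differences. Of the 210 called genes, 203 had groups that did not overlap, 179 were protein coding and 134 had a mean CPM of at least 4. Calls on 2 against 2 samples favour genes without overlap, so the 203 genes give no separate support. Among the 210, 16 were olfactory or vomeronasal receptor genes, the families whose median TPM was used above to gauge the low-level background. The number called was 28 with no filter on low counts, 14 with a CPM of at least 5 in 2 libraries, 119 with DESeq2 size factors and 96 in DESeq2. It was also 96 (86 of them shared) with a block for the part of the library code that same-numbered libraries have in common. It also depended on single libraries: 51 genes were called without Control 1, 56 without Control 2, 896 without cKO 1 and 2267 without cKO 2. Of the 210 genes, 7 were called in all 11 alternatives planned before the data were examined, of which 4 left out a library. They were Ly6k, Midn, Rab43, Sumo2, Fkbp7, Tmem127 and Gm14686, the last chosen after its values were seen. Gm14686 shares 100% of its 50-mers with other genes, and the counts summed over it and the genes that share its sequence changed by a log2 ratio of -0.12. The alternatives start from the same deposited counts or TPM, so they do not test how reads were assigned to genes.

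Sumo2, a ubiquitin-like protein modifier (chromosome 11, 115523102 to 115536276), fell from 123.9 ± 8.74 to 13.4 ± 3.71 CPM, a log2 fold change of -3.20 (SE 0.37, adjusted p = 1.05e-14). Fkbp7, a prolyl isomerase of the endoplasmic reticulum (chromosome 2, 76663044 to 76673116), fell from 62.5 ± 0.52 to 9.81 ± 3.85 CPM (-2.67, SE 0.35, adjusted p = 4.98e-11). Tmem127 (chromosome 2, 127247908 to 127261107) fell from 48.9 ± 3.98 to 8.86 ± 0.24 CPM (-2.47, adjusted p = 1.62e-09). Krr1, needed to process small-subunit ribosomal RNA, fell from 162.0 ± 17.7 to 44.4 ± 14.5 CPM (-1.87, adjusted p = 0.000122). H2-Q1, a class I histocompatibility gene in the variable region of chromosome 17, had the largest fall among the named genes, from 14.4 ± 0.03 to 0.632 ± 0.29 CPM (-4.51, adjusted p = 5.22e-28). The other 7 named genes that fell were Vkorc1l1, Zbtb4, Etohd2, Rab6b, Scml4, Hnrnpa3 and Sspn, with log2 fold changes from -3.99 for Vkorc1l1 to -1.79 for Sspn, which encodes the dystrophin-associated protein sarcospan. Hnrnpa3 rested on Control 2, with 74.1 CPM there and 16.45 CPM in Control 1 against 9.76 and 16.04 CPM in cKO 1 and 2, and was called in 2 of the 11 alternatives. Its log2 fold change was -0.365 without Control 2 and -2.53 without Control 1. Leaving out a library also moved Scml4 to -1.02 (without Control 1), Vkorc1l1 to -4.81 (without cKO 2) and Zbtb4 to -4.06 (without cKO 1). With the change in mean transcript length, which enters these counts, taken out, the log2 change was -2.12 for Vkorc1l1 and -1.80 for Zbtb4, in place of -3.99 and -3.24.

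Ly6k, a membrane-anchored protein of the Ly6 family (chromosome 15, 74796874 to 74799986), rose from 1.68 ± 0.19 to 45.3 ± 11.7 CPM, a log2 fold change of 4.75 (SE 0.38, adjusted p = 4.47e-31). Midn rose from 1.87 ± 0.28 to 18.1 ± 4.29 CPM (3.28, adjusted p = 5.68e-17). Lrrc8a, a subunit of the volume-regulated anion channel, rose from 1.42 ± 1.59 to 174.9 ± 32.4 CPM (6.93, adjusted p = 7.90e-07). Cebpd, a transcription factor of the acute-phase response, rose from 125.5 ± 61.0 to 568.2 ± 146.0 CPM (2.18, adjusted p = 1.28e-05). Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, rose from 13.3 ± 1.53 to 61.0 ± 36.9 CPM (2.20, adjusted p = 2.56e-07). The remaining 7 of the 12 named genes that rose were Eif3j2, Rab43, Rtn4rl2, Grasp, Adgrl1, Vgll2 and Mxi1, with log2 fold changes from 3.49 for Eif3j2 to 1.98 for Mxi1. Rtn4rl2 and Vgll2 were highest in cKO 1, with 16.6 and 42.4 CPM there against 3.08 and 13.1 CPM in cKO 2, and their log2 fold changes without cKO 1 were 1.03 and 1.02. Rtn4rl2 stood at 3.29 without Control 2 and 3.38 without cKO 2. Grasp moved from 2.54 to 1.74 without cKO 1, Arid1a to 1.32 without cKO 2, and Lrrc8a to 6.09 without Control 1 and 9.15 without Control 2. With the change in mean transcript length taken out, the log2 change was 1.55 for Arid1a, 1.42 for Adgrl1 and 1.33 for Mxi1, in place of 2.20, 2.48 and 1.98. Besides the 6 called in every alternative, H2-Q1, Vkorc1l1 and Zbtb4 kept their call with each library left out, and the other named genes lost theirs in at least 1 such fit.

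Some of these counts share sequence with another gene and are uncertain. Eif3j2 shares 91.8% of its 50-mers, nearly all with Eif3j1, and the counts summed over both changed by a log2 ratio of 0.37. Rab43 shares exons with Gm45140, which fell (-3.24), and the sum changed by 0.47. Etohd2 with Tut7 changed by -0.04 as a sum, and Hnrnpa3 with Gm5641 and Gm6793 by -0.76. A sum with a more abundant gene changes little in either case, so a small sum does not show that coverage moved. Lrrc8a overlaps Gm28035 and Ly6k overlaps Gm17189 on the opposite strand, and their sums changed by 5.70 and 4.46. Smaller shares of 50-mers lay in other annotated genes for Sumo2 (19.2%), H2-Q1 (14.96%), Cebpd (13.7%), Adgrl1 (9.97%) and Vkorc1l1 (7.02%). For these genes no other gene reached the minimum set for sharing, so no sum was formed. Exchange of coverage with such genes or with unannotated copies was therefore not tested for them.

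**Figure D2:**
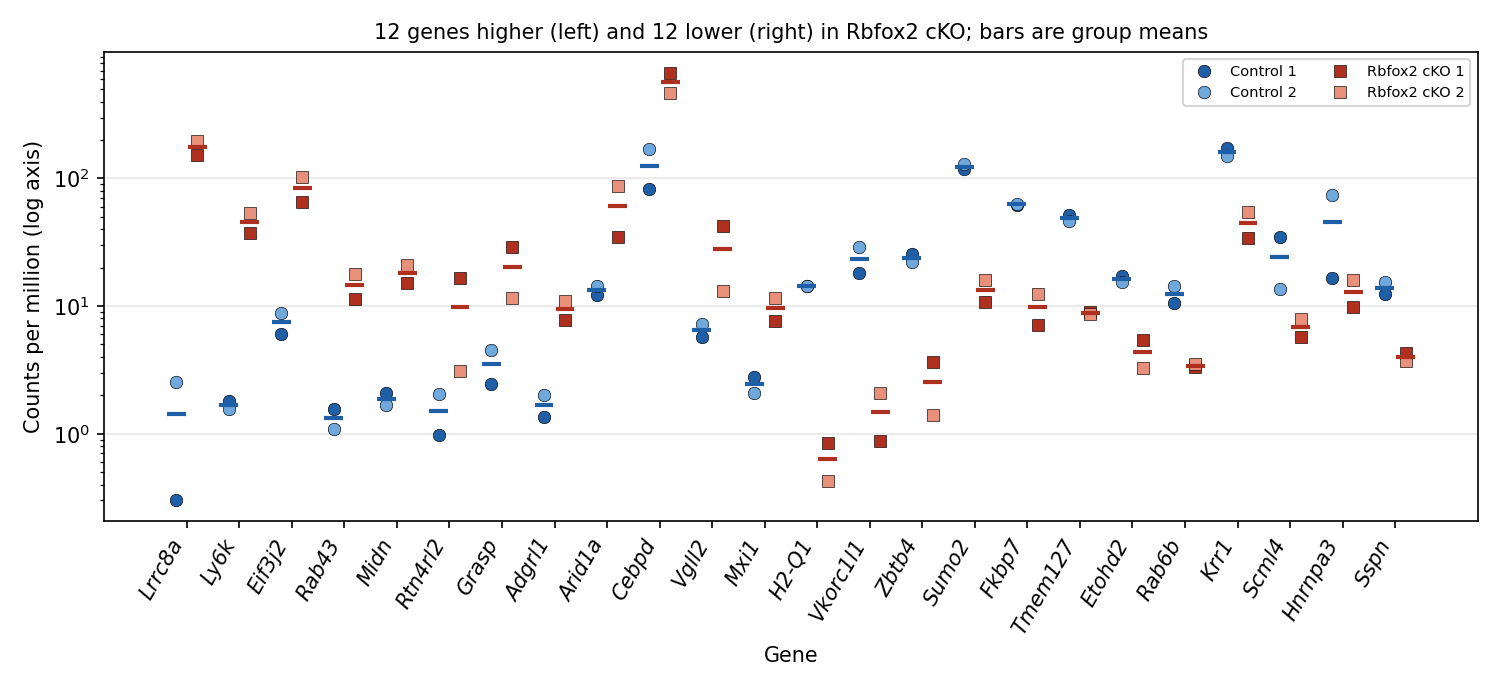
Normalised read counts (CPM) on a log axis for the 12 genes with the largest rise and the 12 with the largest fall among those named by rule, with circles for Control libraries, squares for Rbfox2 cKO libraries and bars for group means. The rule took only genes for which both cKO libraries lie on the same side of both Control libraries. They run from Lrrc8a (1.42 and 174.9 CPM on average) to Sspn (13.9 and 4.01 CPM).

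Haemoglobin genes and Alas2 were higher in cKO. Of 7 tested erythroid markers 5 rose, 0 fell and 2 did not pass, and 5 were higher when adjusted over the list alone. Alas2, the erythroid enzyme that starts haem synthesis, rose from 2.34 ± 1.28 to 8.005 ± 1.497 CPM (log2 fold change 1.77, adjusted p = 0.000252), Hbb-bt by 1.499, Hbb-bs by 1.44, Hba-a2 by 1.44 and Hba-a1, chosen after its values were seen, by 1.36. Of the 11 alternatives, Alas2 was called in 3 and each of the 4 globin genes in 0. Without Control 1 and without Control 2 the log2 fold changes were 1.28 and 2.45 for Alas2, 1.03 and 2.16 for Hbb-bt, 0.98 and 2.08 for Hbb-bs, and 0.86 and 2.35 for Hba-a2. The globin copies share sequence in pairs. Camera gave the list an adjusted p = 1.91e-11, and adjusted p = 0.973 with an estimated correlation. Slc4a1, the anion exchanger of the red cell membrane, stood at 1.01 ± 0.14 CPM in Control and 0.984 ± 0.28 CPM in cKO.

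Immediate early and dissociation response genes included 4 that rose, 0 that fell and 46 that did not pass. Cebpd, Rhob (1.48), Cebpb (1.42) and Dusp5 (1.22) rose, and 5 were higher when adjusted over the list alone, the added gene being Gadd45a, chosen after its values were seen. Of the 11 alternatives, Cebpd was called in 3, none of which left out a library, Rhob and Dusp5 in 1 each and Cebpb in 0. Without cKO 1, Rhob stood at 0.78 and Dusp5 at 0.64, and Cebpb stood at 0.88 without Control 1 and 2.22 without Control 2. The list was higher (adjusted p = 0.0226), with adjusted p = 0.973 with an estimated correlation, and turned lower without cKO 2 (adjusted p = 0.267). Of 39 interferon response genes 0 rose and 0 fell past the threshold, 35 had a positive log2 fold change, and 2 (Stat2 and Ifit1, chosen after their values were seen) were higher when adjusted over the list alone. H2-D1 stood at 1342 ± 36.3 and 1595 ± 466 CPM, Ifitm3 at 593 ± 39.7 and 721 ± 201 CPM, and B2m at 679 ± 77.8 and 666 ± 286 CPM. The list median was 0.33 (adjusted p = 1.08e-05, and adjusted p = 0.973 with an estimated correlation), and the call was lost without cKO 2 (adjusted p = 0.454) and without Control 2 (adjusted p = 0.0501). Endothelial markers had a median of 0.30 with 0 of 14 past the threshold and 0 adjusted over the list alone (adjusted p = 0.0381, and adjusted p = 0.973 with an estimated correlation). Aqp1 stood at 164.9 ± 20.9 and 247.7 ± 24.8 CPM.

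Lists lower in cKO were ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, and mature muscle fibre markers, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. The median log2 fold change was -0.30 over 84 ribosomal protein genes (adjusted p = 1.92e-09), -0.28 over 76 nuclear oxidative phosphorylation genes (adjusted p = 2.52e-09), -0.30 over 13 mitochondrially encoded genes (adjusted p = 0.00119) and -0.30 over 34 fibre markers (adjusted p = 0.000136). For each of them the adjusted p = 0.973 with an estimated correlation. The first 3 rested on cKO 1: its median relative to the Control mean was -0.54 for ribosomal proteins, -0.58 for oxidative phosphorylation and -0.84 for mitochondrially encoded genes, against -0.07, -0.05 and 0.08 in cKO 2. Without cKO 1 their adjusted p values were 0.322, 0.713 and 0.238, the last with the opposite direction. Fibre markers were lower in both, at -0.28 and -0.38. Rplp0 stood at 3185 ± 285 and 2499 ± 373 CPM, Atp5b at 1109 ± 36.3 and 898 ± 211 CPM, and mt-Co1 at 12542 ± 144 and 11899 ± 5080 CPM. Of the 76 nuclear oxidative phosphorylation genes 3 were positive, among them Cox4i1 (0.45). Of the 34 fibre markers 9 were positive. Those with the highest mean CPM changed little, Des by -0.18, Tpm1 by 0.02 and Pygm by 0.08. Acta1, a fibre actin chosen after its values were seen, stood at 29.3 ± 1.38 and 20.2 ± 1.13 CPM.

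The Rbfox family, too small for the set test, had 1 of 3 members lower, Rbfox2. The other 21 lists were not called, with adjusted p from 0.206 to 0.974. Of 19 Notch target genes 0 passed, 14 were positive and the median was 0.17 (adjusted p = 0.324). Of 40 Notch pathway components 0 passed (median 0.04, adjusted p = 0.811), and of 40 muscle targets of Rbfox splicing 0 passed (median -0.01, adjusted p = 0.832). Satellite cell quiescence genes had a median of 0.13 (adjusted p = 0.642), myogenic commitment genes -0.03 (adjusted p = 0.477), cell cycle genes -0.14 (adjusted p = 0.477) and other splicing regulators -0.05 (adjusted p = 0.206), each with 0 past the threshold and 0 adjusted over the list alone. Among p53 targets Plk3, a stress-responsive kinase, rose from 33.2 ± 13.2 to 105.7 ± 21.6 CPM (1.67, adjusted p = 0.000851), and 2 genes were higher when adjusted over the list alone, the other being Phlda3. Among extracellular matrix genes Lamb1, a laminin subunit of the basement membrane, fell from 35.9 ± 4.24 to 14.8 ± 1.304 CPM (-1.28, adjusted p = 0.0255), and 3 genes were lower when adjusted over the list alone, with Mmp2 and Tnc, both chosen after their values were seen, as was Phlda3. Plk3 lost its call when any 1 library was left out, and Lamb1 without Control 1 and without Control 2. Adjusted over the list alone, 1 macrophage gene (Itgam) was lower, 1 tenocyte gene (Tnc) was lower and 1 sex-linked gene (Tsix) was higher, and these were also chosen after their values were seen. No member passed over all genes in the lists of TGF beta and BMP (median 0.06), Wnt signalling (0.11), glycolysis (-0.05), cytoskeleton and adhesion (-0.04), or the markers of fibro-adipogenic progenitors (0.22), macrophages (0.28), lymphocytes (0.40), neutrophils (-0.33), pericytes and smooth muscle (0.02), Schwann cells (0.28), tenocytes (0.09) and sex-linked genes (-0.05). Median, mean and test differed in sign for extracellular matrix, cytoskeleton, tenocyte, sex-linked and Rbfox splicing target genes.

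**Figure D3:**
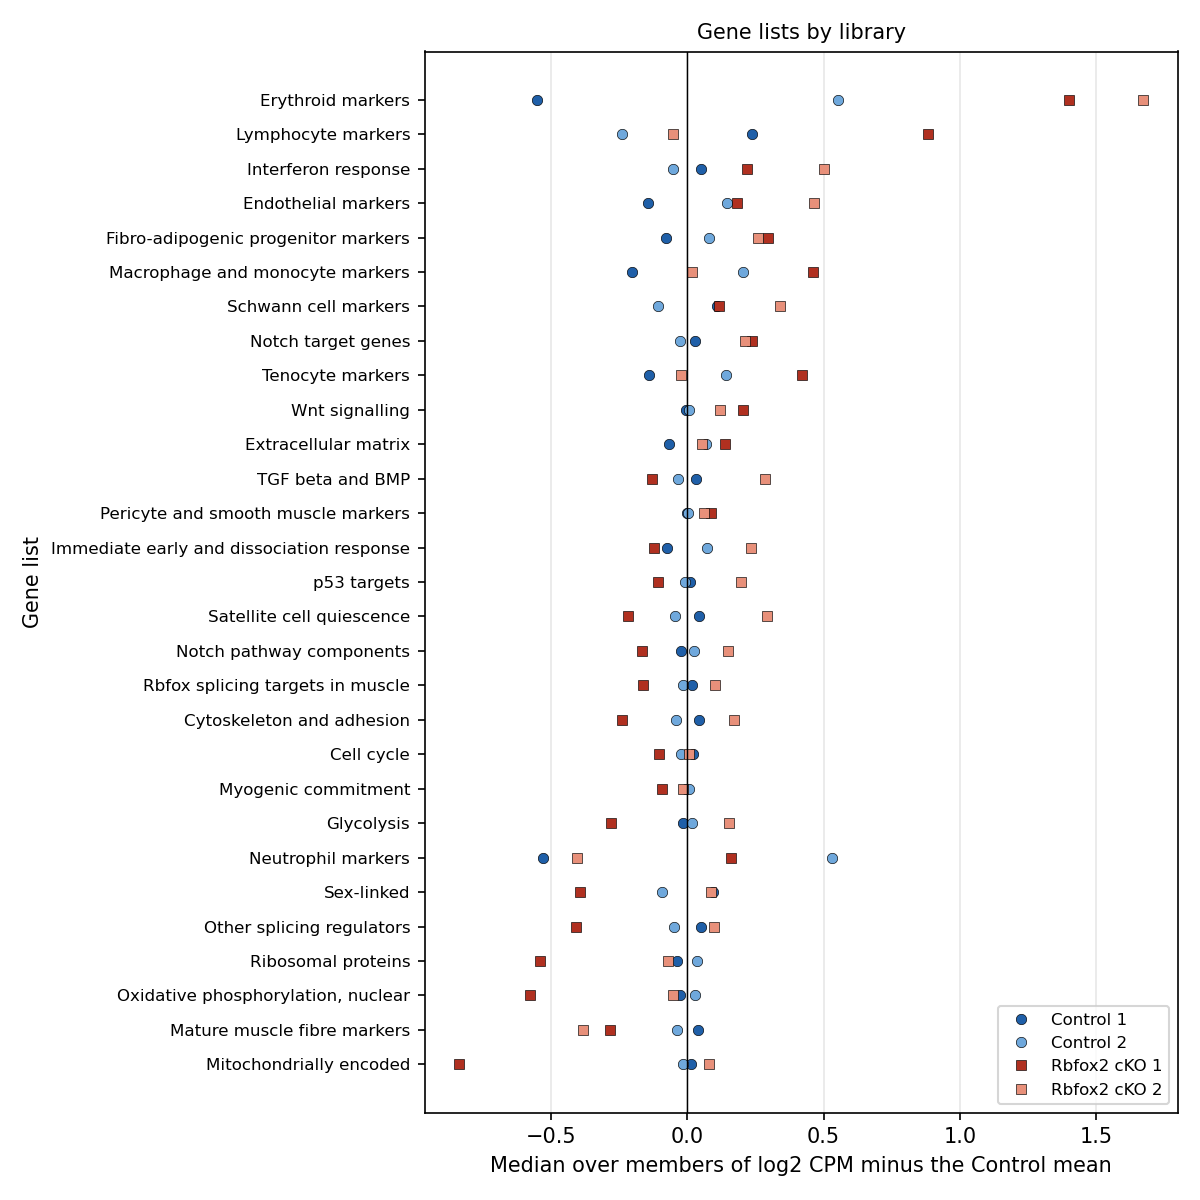
Median over each list's members of the log2 CPM minus the Control mean, for each of the 4 libraries and 29 lists, with circles for Control and squares for Rbfox2 cKO. Erythroid markers lie above both Control libraries in both cKO libraries (1.40 and 1.67), and mitochondrially encoded genes are lower in cKO 1 alone (-0.84 against 0.08 in cKO 2).

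In the TPM, limma called 36 genes higher and 17 lower of 17210 tested, and 2572 had an unadjusted p under 0.05. Of its 53 calls, 31 were also called from the counts, each in the same direction. These were 31 of the 172 genes called from the counts that were tested here. Of the 24 genes named for the largest changes, 10 were called and 14 were not, with adjusted p from 0.0595 for Arid1a to 0.501. Sumo2 fell by 2.71 on the log2(TPM + 1) scale (adjusted p = 0.000162), Ly6k rose by 4.57 (adjusted p = 4.16e-05), Lrrc8a by 5.68 (adjusted p = 0.000327) and Krr1 fell by 1.94 (adjusted p = 0.00192). The TPM come from the same libraries and are not an independent replication.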

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

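The crossed pairing was chosen after seeing the data. The 210 called genes kept their direction in every setting that tested them with all 4 libraries, but the number called moved, and the cause was not tested except where stated. From 139 higher and 71 lower genes, DESeq2 size factors in edgeR gave 66 higher (and 53 lower, a more even split), no filter on low counts 16 and 12 (54471 genes tested), a CPM of at least 5 in 2 libraries 10 and 4 (10011 genes tested), DESeq2 53 and 43, and limma on log2(TPM + 1) 36 and 17. Library totals alone gave 179 and 103, with 74 of the 210 shared and the median of all genes at 0.25 in place of 0.06. Leaving out 1 library, where the lone sample is assumed to vary like the other group, gave 26 to 606 higher and 22 to 2016 lower.

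The correlation of the deviations of same-numbered libraries was -0.12 over tested genes. With the replicate block, edgeR called 61 higher and 35 lower, and 86 were shared. Same-numbered libraries also share a part of their library code, so this block stands for both. The crossed pairing called 155 higher and 88 lower.

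Rbfox2 stayed lower in every setting but lost its call with library totals only (-1.47), no filter (-1.81), a CPM of at least 5 (-1.52), limma on TPM (-1.16) and each library left out (-2.61 to -1.04), with adjusted p from 0.000915 to 1.00 over its alternatives. Without cKO 1, Numb (0.10), Notch2 (0.16) and Myf5 (0.19) turned positive, and with each library left out they ranged from -0.57 to 0.10, from -0.59 to 0.16 and from -0.72 to 0.19. Myod1, near 0 throughout, turned negative with DESeq2 size factors (-0.0396), no filter (-0.000408), DESeq2 (-0.0396), without Control 1 (-0.05) and without cKO 2, with a range from -0.16 to 0.14 over the libraries left out.

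From 4 lists higher and 4 lower, DESeq2 size factors gave 2 higher, an estimated inter-gene correlation 0 and 0, fry 0 and 0, and each library left out 1 to 14 higher and 1 to 13 lower. The immediate early list turned lower without cKO 2 (adjusted p = 0.267) and mitochondrially encoded genes turned higher without cKO 1 (adjusted p = 0.238), with adjusted p over the libraries left out from 5.37e-08 to 0.569 for the first and from 1.63e-16 to 0.238 for the second.

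For limma on TPM, from 36 and 17, a pseudocount of 0.1 gave 62 and 40, no filter 285 and 119, a mean TPM of at least 5 13 and 5, and each library left out 12 to 470 higher and 6 to 138 lower. The pair check over genes with a mean count of at least 100 gave 89.4 for Control and 138.9 for cKO. For named genes and lists, 427 values in other settings kept direction and side of the threshold, 204 lost the call, 8 gained it and 10 reversed. The variants of transcript usage were not run because the TPM are per gene.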

Other observations

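The tests below on haemoglobin, shared sequence and the position of calls were chosen after the result was seen, and those on the added gene lists and on transcript length were written before their results were seen. The added lists themselves were drawn up after 7 of their genes had been seen in the table of all genes, and those genes were left out of the tests. The enzymes of serine synthesis were lower in cKO. Phgdh fell from 50.3 ± 10.2 to 15.8 ± 2.43 CPM (SD, n = 2; log2 fold change -1.67, edgeR adjusted p = 0.000417), Psat1 from 120.0 ± 31.3 to 41.9 ± 20.8 CPM (-1.52, adjusted p = 0.00503) and Psph from 20.6 ± 2.89 to 8.12 ± 3.04 CPM (-1.34, adjusted p = 0.0115). With the change in mean transcript length taken out, the log2 change was -1.41 for Psat1 and -0.88 for Psph. Of the 11 alternatives, Phgdh was called in 7 and Psat1 and Psph in 3 each. These are known targets of the transcription factor ATF4, which activates amino acid synthesis, uptake and tRNA charging, and a hypothesis was that these genes fell as a group. Of the list's 46 tested members 5 were called, all of them seen beforehand and left out of the test: the 3 enzymes, Stc2 (-1.52, adjusted p = 0.00426) and Got1 (-1.35, adjusted p = 0.0109). Of the other 41, 38 were negative, with a median of -0.63, among them Asns (-1.17), Mthfd2 (-1.21) and Aldh18a1 (-1.14). Camera gave p = 2.85e-23 at the preset correlation and p = 0.137 with an estimated one of 0.57. The median relative to Control was -0.89 in cKO 1 and -0.40 in cKO 2, and leaving out any library kept the direction (-1.01 to -0.39). The bound set beforehand against a shared fall was also met, since this median lay above the -1.52 of the 3 enzymes by more than the SD of 0.40. Those 3 were picked because they were called, which by itself widens that gap, so the test leaves the hypothesis open, and cKO 1, where ribosomal protein and mitochondrial genes were also lower, gives the larger share.

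Edem1, which takes part in the disposal of misfolded proteins of the endoplasmic reticulum, rose from 64.6 ± 8.81 to 189.9 ± 48.4 CPM (1.56, adjusted p = 0.0048), and was called in 6 of the 11 alternatives. The hypothesis that genes of the ATF6 and XBP1 stress response rose with it was not borne out: all 24 other members were negative, with a median of -0.65 (SD 0.21) and camera p = 6.24e-18 in the lower direction (p = 0.145 with an estimated correlation of 0.69). Pdia4 (-0.90), Dnajb11 (-0.89) and Pdia3 (-0.86) did not pass singly. The median was -1.03 in cKO 1 and -0.35 in cKO 2, and -0.33 without cKO 1. The fall was seen only in this test and was not predicted.

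Haemoglobin RNA was higher in cKO, at 503 and 599 CPM for the globin sum in cKO 1 and 2 against 128 and 284 CPM in Control 1 and 2. The higher background of cKO 1 is argued against, since cKO 2 exceeded the higher Control library by log2 1.08. A lower share of satellite cells would raise every other cell type alike. The upper quartile of log2 fold changes reached 0.66 at most over 8 other cell type lists, below the lowest change of a globin gene or Alas2 (1.36). The globin genes and Alas2 were picked because they were called, which by itself widens that gap, so the comparison does not decide this. The log2 ratio of alpha to beta globin ranged over 5.18% of the range of the globin sum, as either a single source in varying amounts or joint regulation of these genes would give. Slc4a1, another red cell gene, stood at 1.01 and 0.984 CPM, near the floor, so carry-over of red cell RNA cannot be told apart from regulation by genotype.

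Genes that were called shared sequence with another gene more often than matched genes, 54 of 210 against 28 of 210 (Fisher's exact test, two-sided p = 0.00196). When a gene was summed with those that share its sequence, the change dropped below 50% of its own for 35 of the 54, against 6 of 28 matched genes (Fisher's exact p = 0.000375). This comparison does not decide whether coverage moved between copies, because the called genes were selected for a large change of their own (median size 1.90 against 0.25 in matched genes). Exchange with an annotated gene is argued against for 79 called genes that have no 50-mer in common with one and no exon overlap, such as Fkbp7 and Tmem127, while unannotated copies were not searched. A change in mean transcript length, which enters these counts, was compared with the fold change in 154 called genes that share no sequence at the set minimum. It reached 50% or more of the fold change in 9.09% of them (exact 95% interval 5.06% to 14.8%), too few for it to be their general explanation. A strain difference between the groups, genotype itself or an unannotated copy remains open.

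Calls were denser on chromosome 15, which carries Rbfox2, with 16 of 1321 tested genes (1.21%) against 0.524% elsewhere, Rbfox2 left out. A floxed allele may carry a flanking segment of another strain. Within 10 Mb of Rbfox2, 4 of 440 genes were called (Ly6k, Gm17189, Csf2rb and Lgals2), 0.909% against 0.544% elsewhere (Fisher's exact p = 0.31, odds ratio 1.68, 95% interval 0.451 to 4.39), while on the rest of the chromosome 12 of 881 were (1.36%, odds ratio 2.598, Fisher's exact p = 0.00361). Of the 4 genes near Rbfox2, 25% shared sequence at the set minimum, and with 4 genes neither explanation can be told apart from a direct effect of genotype, while a longer segment remains open. On chromosome 17 from 33 to 37 Mb, 5 of 243 tested genes were called (H2-Q1, Gm20507, Gm11127, Gm7030 and Ring1). That was 2.06% against 0.538% elsewhere (odds ratio 3.88, 95% interval 1.24 to 9.33, Fisher's exact p = 0.0112). Gm20507, Gm11127 and Gm7030 share sequence with other genes. Gm11127 and Gm7030 share it with each other, as do Ly6k and Gm17189 near Rbfox2. Fisher's exact test takes the genes of such a pair as independent, though their calls may not be separate. The region on chromosome 17 was also chosen after the calls were seen, so the density does not decide whether the groups differ in strain there.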
